A study of Mus musculus with 18 samples.

How the data were processed

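The series holds bulk RNA sequencing of primary cardiac fibroblasts from neonatal CD1 mice, reprogrammed with a retrovirus that carries Mef2c, Gata4 and Tbx5, in 18 samples of 2 sets. Per the labels' protocols, RNA was extracted with Trizol and 1 µg of total RNA went into each library, and no sorting of the cells is named. Per the file headers, the deposited values are raw counts per gene from featureCounts 2.0.6, run strand-specifically on the UCSC gene annotation of mm10. The command asked for no counting of read pairs, so each mate counted by itself, and 65.86% of counts from 1 to 20 were even in the second set and 72.51% in the first. Neither multi-mapping reads nor reads in several genes were counted. FastQC and DESeq2 are named in the submitters' processing notes, and the aligner is not given in the sources used here.

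The groups and comparisons were fixed before the data were examined. The second set has 12 libraries in 4 groups of 3 (shNT, shMtfr1l, shOpa1 and the double knockdown). Its comparisons were shMtfr1l against shNT, shOpa1 against shNT, the double knockdown against each of the other 3 groups, and the interaction of the 2 knockdowns. The first set has 6 samples, 1 per condition in the labels. The count columns of its 2 reprogramming samples could be tied to the labels, 3 columns for each, and were summed and counted as 1 replicate, without a test. Columns of 1 sample differed by 4.36 to 7.52 in chi-square per gene, close to the separate libraries of the second set, so they may be more than repeated reads of 1 library. The 4 fibroblast samples are not analysed here, since their 12 count columns could not be tied to the labels. For that reason 3 fits planned for the first set were not run. The first-set pair was used for directions, for list percentiles and, with set as a covariate, as an added pair.

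Counts were scaled with TMM (trimmed mean of M values), genes with low counts were removed with filterByExpr, and groups were compared with edgeR 4.0.16 (quasi-likelihood test, 1 coefficient per group, 8 residual degrees of freedom) in R 4.3.3. P-values were adjusted with the Benjamini-Hochberg method and called under 0.05. Of 23420 genes in the files 14162 were tested in the second set and 15198 were kept in the first. The common biological coefficient of variation was 12.04%. Depth ran from 16205862 to 25317069 counts in the second set, and a floor of 3 counts lay between 0.118 and 0.185 CPM. The floor covers counting error alone, while the SDs and SEs given also hold the spread between libraries. As each mate counted by itself, 3 counts can stand for as few as 2 fragments, so the floor is less sure than 3 independent reads would make it. Libraries of 1 group differed by 5.37 to 10.29 in chi-square per gene, so none was a copy of another. CPM values are TMM-scaled, and log2 values of single libraries use a prior count of 2.

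On simulated data with 50 genes changed at each fold, the comparison of shMtfr1l with shNT recovered 32% of genes at 1.25-fold, 50% at 1.5-fold, 78% at 2-fold and 84% at 4-fold over 13960 genes, with 3.94% of its calls false. The interaction recovered 8%, 30%, 54% and 80% over 13947 genes. False calls stayed at or under 9.22% in every comparison. A 1.25-fold rise put into the sarcomere list came back with a median of 1.294. With no rise put in the median was 1.035 and the camera test did not pass (adjusted p = 0.435), yet it lay at percentile 98.5 of random lists, so a percentile a little past 97.5 is weak evidence. The simulated genes were drawn independently, while members of real lists correlate (estimated at 0.171 for the sarcomere list). The simulation therefore cannot show how the list tests and percentiles behave on correlated lists.

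33 gene lists were fixed in advance and 31 were tested. Mitochondrially encoded genes have no member in the files and red blood cell genes none past the filter. The tested lists cover the sarcomere, calcium handling and channels, cardiac transcription factors, other cardiomyocyte genes, fibroblast identity, collagen and matrix, myofibroblast, smooth muscle, endothelial, macrophage and leukocyte, epicardial and mesothelial and Schwann markers. They also cover the cell cycle, the respiratory chain, the tricarboxylic acid cycle, fatty acid oxidation, glycolysis and hypoxia, mitochondrial dynamics, biogenesis and mitophagy, the integrated stress, unfolded protein, interferon, inflammation, p53 and antioxidant responses, sterol and fatty acid synthesis, Notch, Wnt and BMP targets, chromatin barriers and both ribosomes. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with a correlation estimated from the data, and with fry.

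Genes were named by a rule written in advance: the targeted genes, the 10 largest rises and 10 largest falls per comparison among called genes with a mean of at least 2 CPM whose groups did not overlap, and up to 4 members per list with the smallest adjusted p. The text names part of these. The choice was made after their dependence on single libraries had been seen, and it favoured genes that kept their call. Over all genes of the rule that were called, leaving out 1 library ended the call of 26 of 114 for shMtfr1l against shNT, 11 of 131 for shOpa1 against shNT, 17 of 130, 22 of 129 and 37 of 81 for the double knockdown against shNT, shMtfr1l and shOpa1, and 37 of 75 for the interaction. Among the named genes this held for 3 of 45, 0 of 48, 2 of 33, 0 of 30, 0 of 22 and 18 of 50. Leaving 1 replicate number out of every group ended the call of 42, 16, 30, 28, 52 and 52 of all rule genes and of 7, 0, 2, 0, 4 and 30 of the named ones, in the same order. The leukocyte covariate ended 0, 0, 15, 23, 10 and 15 of all and 0, 0, 0, 0, 0 and 7 of the named. Some of these the rule gave for another comparison, since the interaction is printed for every named gene where it passed. The named genes thus look firmer than those of the rule as a whole. Some genes of the rule are not reported here.

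The titles give libraries with 1 replicate number the same day, so the number was taken as a pairing by label. Deviations of libraries with the same number correlated at -0.189 to 0.122 across genes (median -0.0019), and 4 of 12 libraries were closest to one of their own number. The alternatives planned were DESeq2 size factors, no filter, the DESeq2 1.42.0 Wald test, the replicate number as a block, each library left out, the 2 groups alone, the first-set pair added, and a prior count of 0.5 or 10 and an adjusted p of 0.01 for the first-set directions. A covariate of leukocyte markers and the removal of each replicate number from every group were added after the data were seen.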

Results

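RNA sequencing was used to follow direct cardiac reprogramming, in which cardiac fibroblasts are driven towards a cardiomyocyte-like state by a retrovirus that carries the cardiac transcription factors Mef2c, Gata4 and Tbx5 on 1 transcript. The cells were primary cardiac fibroblasts of neonatal CD1 mice. The series asks how loss of Mtfr1l, a mitochondrial outer membrane protein of the fission regulator family, acts on this process. Short hairpin RNAs (shRNAs) lowered Mtfr1l, Opa1 (the GTPase that fuses inner mitochondrial membranes) or both, and a non-targeting shRNA (shNT) served as the control. The second of 2 sample sets held 12 reprogramming libraries in 4 groups of 3: shNT, shMtfr1l, shOpa1 and the double knockdown. Their totals, for replicates 1, 2 and 3, were 16205862, 23527030 and 21480191 gene counts for shNT and 19740165, 17175325 and 17366829 for shMtfr1l. They were 20194675, 21164487 and 20769664 for shOpa1, and 23718132, 25317069 and 21590643 for the double knockdown. The first set held 6 samples, 1 per condition in the labels. Its shNT and shMtfr1l reprogramming samples from day 7 are used here, with 67068683 and 62923192 counts over 3 count columns each, and its 4 fibroblast samples are not analysed here. The titles tie replicate numbers 1, 2 and 3 of the second set to days 7, 8 and 9. The labels call its libraries biological replicates without saying whether they came from separate animals or isolations, so p-values measure only the spread between these libraries.

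The targeted genes followed the titles in every library of the second set. Mtfr1l (mm10 chromosome 4, 134525555 to 134535387, minus strand) stood at 71.9 ± 4.17 CPM (counts scaled to library size; SD, n = 3) in shNT, 16.4 ± 2.88 in shMtfr1l, 69.6 ± 3.34 in shOpa1 and 27.2 ± 4.15 in the double knockdown. Opa1 (chromosome 16, 29579334 to 29654602, plus strand) stood at 63.1 ± 8.33, 72.1 ± 1.35, 8.96 ± 3.16 and 18.3 ± 2.34 CPM in the same order. Mtfr1l fell 4.38-fold in shMtfr1l (log2 fold change -2.13 ± 0.11, SE; adjusted p = 2.81e-16, edgeR quasi-likelihood test) and Opa1 fell 7.04-fold in shOpa1 (-2.82 ± 0.19; adjusted p = 7.52e-08). The titles name shOpa1 for all libraries with Opa1 knockdown, while their genotype field reads shOpa1, shOpa2 and shOpa3 over replicates 1, 2 and 3, alone or beside shMtfr1l. What the numbers stand for is not given in the sources used here. Opa1 lay between 6.85 and 20.7 CPM in each of these libraries and between 57.0 and 73.4 CPM in the others. Opa3, looked at because of that field, was not lowered (52.5 ± 2.50 CPM in shOpa1 and 46.7 ± 2.81 in shNT, adjusted p = 0.181; 54.2 and 51.0 CPM in replicate 3 of shOpa1 and of the double knockdown), so the groups follow the titles here. Both targets were less depleted in the double knockdown than in the single ones. Mtfr1l was 1.66-fold higher there than in shMtfr1l (adjusted p = 5.27e-06) and Opa1 was 2.04-fold higher than in shOpa1 (adjusted p = 0.00745). The Opa1 difference did not pass when replicate 1 was left out of every group (adjusted p = 0.188). Neither shRNA moved the other's target past the threshold (Opa1 in shMtfr1l, adjusted p = 0.583; Mtfr1l in shOpa1, adjusted p = 0.787). An exact 2-sided permutation test of 3 against 3 libraries cannot go below 0.1, the value it gave for each knockdown.

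**Figure D1:**
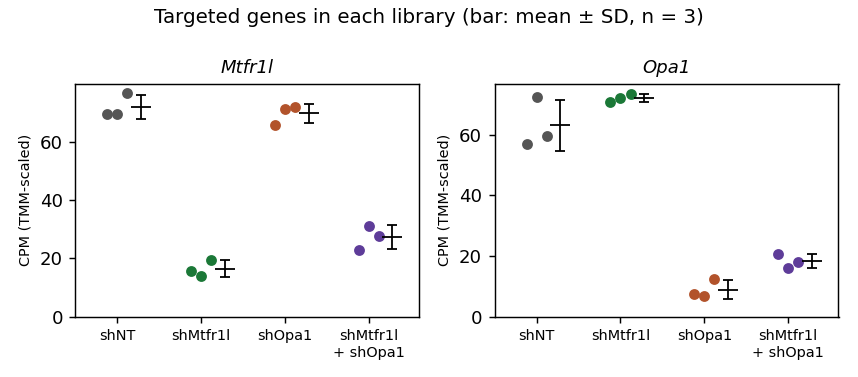
Mtfr1l and Opa1 in each library of the second set, in TMM-scaled CPM, with 1 point per library and a bar for the mean ± SD of each group (n = 3). Mtfr1l has its lowest mean in shMtfr1l (16.4 CPM) and Opa1 in shOpa1 (8.96 CPM), and in the double knockdown both means lie above these (27.2 and 18.3 CPM).

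Knockdown of Mtfr1l during reprogramming was followed by higher levels of contractile genes and lower levels of fibroblast and epicardial genes. Myh6, the alpha myosin heavy chain of adult mouse myocardium (chromosome 14, 54941921 to 54966607), rose 4.82-fold, from 50.8 ± 5.18 to 245 ± 16.3 CPM (SD, n = 3; adjusted p = 1.34e-05). Saa3, an acute phase protein, fell 10.5-fold (10.99 ± 4.47 to 1.03 ± 0.44 CPM; adjusted p = 1.14e-07). Of 14162 genes tested, 788 were higher and 735 lower in shMtfr1l than in shNT at an adjusted p under 0.05. Of these, 74 were more than 2-fold higher and 41 more than 2-fold lower. The 3 libraries of each group did not overlap for 1467 of the 1523 genes. By chance 2 groups of 3 do not overlap for 10% of genes, and a call from the same libraries favours genes whose groups part. Such counts, here and in the other comparisons, are therefore no separate support for the calls. With the libraries of 1 replicate number left out of every group, 790 genes (without number 1; 331 higher and 459 lower) and 878 genes (without number 2; 454 higher and 424 lower) passed, so the balance of rises and falls depends on the libraries.

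The sarcomere list had the smallest adjusted p of the 31 tested lists at camera's preset correlation. With an estimated correlation it shared the smallest value with the calcium, fibroblast, epicardial and tricarboxylic acid cycle lists. Of 35 sarcomere genes, 26 rose, none fell and 9 did not pass (28 rose adjusted over the list alone), with a median of 1.42-fold. The camera test gave adjusted p = 5.54e-27, and adjusted p = 0.0151 with an estimated correlation. Myh7, the beta myosin heavy chain, rose 3.20-fold, Csrp3, a Z-disc protein, 2.42-fold, Myom2, an M-band protein, 1.75-fold, and Ldb3, also of the Z-disc, 1.54-fold. Of 29 calcium handling and channel genes, 12 rose and none fell (14 and 1 adjusted over the list alone; adjusted p = 3.94e-09, and 0.0151 with an estimated correlation). They included Sln, a small inhibitor of the calcium pump (3.35-fold, 27.5 ± 3.04 to 92.0 ± 6.76 CPM), Trdn, which anchors calsequestrin (2.23-fold), Atp2a2, the calcium pump itself (1.70-fold), and the potassium channel gene Kcnj5 (1.54-fold). Mb (myoglobin) rose 3.18-fold and Corin, the protease that activates natriuretic peptides, 2.56-fold, while Nppa, the atrial natriuretic peptide, fell 1.63-fold (adjusted p = 0.00113, but 0.21 without replicate 1 of every group and 0.064 with the first-set pair added). Their list of other cardiomyocyte genes had 8 of 20 higher and 2 lower (10 and 2 adjusted over the list alone; adjusted p = 1.34e-04, but adjusted p = 0.0996 with an estimated correlation). Of 19 cardiac transcription factors 6 rose (7 adjusted over the list alone; adjusted p = 0.00871, but adjusted p = 0.269 with an estimated correlation), led in size by Hopx (3.20-fold). The 6 include Mef2c, Gata4 and Tbx5, which the vector carries. This list's call ended without shMtfr1l replicate 1 (adjusted p = 0.0613). Frem2, an extracellular matrix protein, rose 3.87-fold.

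The 3 vector factors belong to the cardiac transcription factor list and are counted among its rises. They were slightly higher in shMtfr1l, Mef2c 1.18-fold (adjusted p = 0.0122), Gata4 1.12-fold (adjusted p = 0.0468) and Tbx5 1.15-fold (adjusted p = 0.0204). Gata4 and Tbx5 are named because the vector carries them, after their values were seen. Counts of these genes hold endogenous and vector transcripts alike. Mef2c did not pass without shNT replicate 1 (adjusted p = 0.103), without shMtfr1l replicate 1 (adjusted p = 0.111), or when the first-set pair was added (adjusted p = 0.617). Gata4 and Tbx5 did not pass either without shNT replicate 1 or 2 or shMtfr1l replicate 1, or with the first-set pair (adjusted p from 0.0796 to 0.831), and Gata4 also not without shMtfr1l replicate 2 (0.0919), with the replicate number as a block (0.0777), with the 2 groups alone (0.0841) or with DESeq2 size factors (0.0577). Without replicate 1 of every group none of the 3 passed (adjusted p from 0.459 to 0.63), and without replicate 2 Gata4 (0.277) and Tbx5 (0.101) did not.

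Of 30 fibroblast identity genes, 14 fell and 2 rose after Mtfr1l knockdown (16 and 3 adjusted over the list alone; adjusted p = 2.96e-09, and 0.0151 with an estimated correlation). Mfap5, a microfibril glycoprotein, fell 2.05-fold, Tcf21, a transcription factor of epicardium-derived fibroblasts, 1.44-fold, and Fbln2 (fibulin 2) 1.38-fold. Of 43 collagen and matrix genes 20 fell and 5 rose (21 and 9 adjusted over the list alone; adjusted p = 1.16e-06, but adjusted p = 0.269 with an estimated correlation). Col3a1 fell from 7256 ± 175 to 4574 ± 102 CPM (1.59-fold), Lox, the enzyme that crosslinks collagen, 1.66-fold, and Fmod (fibromodulin) 1.68-fold. Of 14 epicardial and mesothelial markers 7 fell and none rose (9 and 1 adjusted over the list alone; median 1.57-fold lower; adjusted p = 4.47e-08, and 0.0151 with an estimated correlation), among them Bnc1 (2.38-fold), Lrrn4 (1.85-fold) and Msln (mesothelin, 1.62-fold). Of 33 inflammation genes 8 fell and none rose (8 adjusted over the list alone; adjusted p = 5.29e-04, but adjusted p = 0.136 with an estimated correlation). Besides Saa3 they included complement C3 (2.01-fold), and the leukocyte adhesion molecules Vcam1 (1.59-fold) and Icam1 (1.56-fold).

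Of 29 sterol and fatty acid synthesis genes 15 fell and none rose (20 adjusted over the list alone; adjusted p = 2.56e-11, and 0.0299 with an estimated correlation), including Hsd17b7 (1.67-fold), Sqle (1.40-fold) and Insig1 (1.35-fold). Of 29 Notch, Wnt and BMP targets 8 fell and 1 rose (10 and 3 adjusted over the list alone; adjusted p = 9.33e-04, and 0.0472 with an estimated correlation). Sfrp2, a secreted Wnt modulator, fell 3.18-fold, the Notch ligand Jag1 1.61-fold and the Notch target Hes1 1.52-fold. Of 26 genes of the tricarboxylic acid cycle and pyruvate entry 9 rose and none fell (9 adjusted over the list alone; adjusted p = 5.29e-05, and 0.0151 with an estimated correlation), with Pdk2 at 1.57-fold, Mdh1 at 1.24-fold and Idh2 at 1.23-fold. These 3 genes each lost their call when 1 replicate number was left out of every group (adjusted p = 0.0542 without 1, 0.0777 without 3 and 0.0501 without 2). Of 77 nuclear respiratory chain genes 12 rose and 2 fell (13 and 2 adjusted over the list alone; adjusted p = 9.8e-04, but adjusted p = 0.413 with an estimated correlation and 0.0542 without shNT replicate 3). Of 76 cytosolic ribosomal protein genes 13 fell and none rose (17 adjusted over the list alone; adjusted p = 1.38e-07, but adjusted p = 0.269 with an estimated correlation).

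The remaining lists were called weakly or not at all. Cell cycle genes (3 of 44 higher, none lower, 2 adjusted over the list alone, adjusted p = 0.0246), unfolded protein response genes (4 of 23 higher, none lower, 6 adjusted over the list alone, 0.0209), interferon genes (2 of 44 higher, none lower, 2 adjusted over the list alone, 0.0442) and p53 and apoptosis genes (3 of 27 lower, none higher, 3 adjusted over the list alone, 0.0154) passed camera's preset correlation and gave adjusted p = 0.476, 0.725, 0.17 and 0.0632 for cell cycle, interferon, unfolded protein response and p53 with an estimated correlation. The cell cycle call ended without shMtfr1l replicate 2 (adjusted p = 0.157), shNT replicate 2 (0.0574) or shNT replicate 3 (0.0872), and the unfolded protein response call without shNT replicate 3 (0.0601). The interferon call ended without shNT replicate 2 (adjusted p = 0.38) and with the first-set pair added (adjusted p = 0.697), and its median turned to -0.031 without shMtfr1l replicate 3. Not called were myofibroblast (3 higher and 7 lower of 26), smooth muscle (2 and 1 of 16), endothelial (1 and 1 of 17), macrophage and leukocyte (0 and 0 of 21), Schwann and neural crest (0 and 0 of 9), fatty acid oxidation (4 and 0 of 29), glycolysis and hypoxia (2 and 4 of 29), mitochondrial dynamics (2 and 1 of 35), mitochondrial biogenesis (3 and 0 of 34), mitophagy and autophagy (2 and 3 of 31), integrated stress (2 and 6 of 42), NRF2 and antioxidant (1 and 3 of 30), chromatin barrier (4 and 1 of 24) and mitochondrial ribosome genes (0 and 0 of 76). Their adjusted p ran from 0.057 to 0.908. The leukocyte list depended on single libraries, with a median of -0.58 and a downward test without shMtfr1l replicate 2 (adjusted p = 5.23e-06) and of 0.50 and an upward test without shMtfr1l replicate 3 (adjusted p = 0.0254). Median, mean and test differed in sign for the leukocyte list (median log2 fold change 0.11, mean 0.038, camera direction down) and, with medians within 0.02 of 0, for mitochondrial dynamics, mitophagy and the mitochondrial ribosome.

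**Figure D2:**
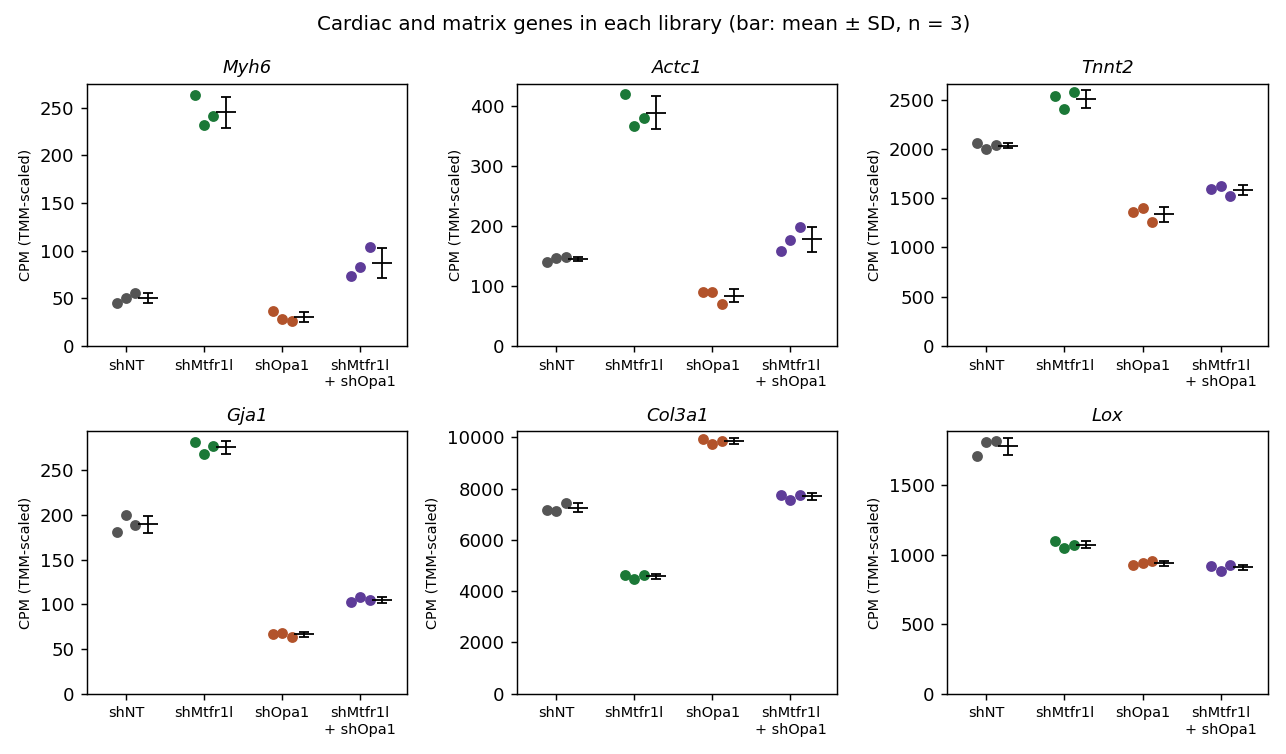
CPM (TMM-scaled) of 4 cardiac genes (Myh6, Actc1, Tnnt2, Gja1) and 2 matrix genes (Col3a1, Lox) in each of the 12 libraries, with 1 point per library and a bar for the mean ± SD of each group (n = 3). Myh6 and Actc1 are highest in shMtfr1l (245 and 389 CPM) and lowest in shOpa1 (30.4 and 84.1 CPM), and Lox is highest in shNT (1782 CPM).

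The same knockdown in the first set has 1 labelled sample per shRNA, each with 3 count columns. The columns of 1 sample differed by 4.36 to 7.52 in chi-square per gene, close to the 5.37 to 10.29 between second-set libraries of 1 group, so they may be separate libraries. What they are is not given in the sources used here, and they were summed without a test. Mtfr1l stood at 79.2 CPM in shNT and 8.73 CPM in shMtfr1l there, where the labels give a knockdown of 85%. Of the 1519 genes called in the second set and measured in both, 1248 (82.16%) had the same sign in the first-set pair, against 62.35% of all 14015 genes measured in both. The 2 sets share no library. Myh6 stood at 1162 and 3481 CPM, Actn2 at 59.7 and 250 CPM and Col3a1 at 1868 and 776 CPM, in shNT and shMtfr1l. Against a general cardiac rise and fibroblast fall, Nppa stood at 23.7 and 6.43 CPM and Pln (phospholamban) at 6.99 and 3.70 CPM, while Col1a1 (9787 and 9728 CPM) and Postn (1063 and 1092 CPM) hardly differed. In the second set Col1a1 was called higher in shMtfr1l (log2 fold change 0.16, adjusted p = 0.0195, edgeR quasi-likelihood test) and Postn was not called (0.10, adjusted p = 0.134). The tables were normalised separately, so the first-set levels cannot be set against those of the second set. The sarcomere list had a median log2 difference of 0.27 and the calcium list of 0.42, both at percentile 100 among 10000 random lists of the same size and expression. The epicardial list (-0.82), the leukocyte list (-0.75) and the interferon list (-0.56) lay at percentile 0. Cell cycle genes (0.39) and cytosolic ribosome genes (0.095) lay at percentiles 100 and 99.6, the latter opposite in sign to the second set (-0.17). The interferon list and the cardiac transcription factor list (-0.095, percentile 15.38) also went against the second set, where their medians were 0.22 and 0.12. Of 31 lists 10 had medians of opposite sign in the 2 sets, and these were 3 of the 17 called in the second set. The other 7 were smooth muscle (-0.48, percentile 0, against 0.07 in the second set), endothelial (-0.51, percentile 0.75, against 0.16), leukocyte (against 0.11), mitochondrial ribosome (0.19, percentile 100, against -0.016), mitochondrial dynamics (0.13, percentile 99.3, against a median within 0.02 of 0), glycolysis and hypoxia (0.09, percentile 95.3, against -0.043) and antioxidant genes (0.064, percentile 82.1, against -0.048).

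Opa1 knockdown gave the largest number of changed genes of the 5 comparisons between groups and lowered many cardiac genes. Hcn4, the pacemaker channel, fell 6.17-fold (7.27 ± 0.96 to 1.17 ± 0.37 CPM; SD, n = 3), Tnni1, the slow skeletal and fetal cardiac troponin I, 6.04-fold, and Rbm24, a muscle splicing regulator, 4.31-fold. Gja1 (connexin 43) fell 2.86-fold, from 190 ± 9.63 to 66.4 ± 2.61 CPM (adjusted p = 3.45e-21). Xirp2, an actin-binding protein of striated muscle, went the other way and rose 16.1-fold (1.24 ± 0.43 to 19.4 ± 3.28 CPM; adjusted p = 1.67e-16). Of 14162 genes, 2025 were higher and 2139 lower in shOpa1 than in shNT, 158 of them more than 2-fold higher and 321 more than 2-fold lower. The groups did not overlap for 3957 of the 4164.

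Of the calcium and channel genes 16 fell and 2 rose of 29 (the same counts adjusted over the list alone; adjusted p = 1.32e-05, but adjusted p = 0.0533 with an estimated correlation). Kcnj5 fell 1.62-fold and the sodium calcium exchanger Slc8a1 1.51-fold, while Asph rose 1.47-fold. Of 35 sarcomere genes 16 fell and 7 rose (17 and 7 adjusted over the list alone; adjusted p = 0.00647, but adjusted p = 0.535 with an estimated correlation), with Tnnt2, cardiac troponin T, at 1.52-fold lower and the atrial light chain Myl4 at 1.68-fold lower. Among other cardiomyocyte genes 10 of 20 fell and 2 rose (the same adjusted over the list alone; adjusted p = 0.00425, but adjusted p = 0.248 with an estimated correlation). Eno3, muscle enolase, fell 2.44-fold and Nppa 2.31-fold, while Synpo2l rose 2.60-fold. Pvalb (parvalbumin) fell 4.30-fold and Mrap2, a melanocortin receptor accessory protein, 6.06-fold.

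Of 42 integrated stress response genes 23 rose and 4 fell (the same adjusted over the list alone; adjusted p = 2.05e-06, but adjusted p = 0.18 with an estimated correlation). Atf3 rose 2.39-fold, the amino acid transporter Slc7a1 1.55-fold and the alanyl-tRNA synthetase Aars 1.33-fold, while Ddit4, an inhibitor of mTORC1, fell 2.07-fold. The mitochondrial chaperones Hspd1 (1.72-fold) and Hspa9 (1.29-fold) rose in a mitochondrial biogenesis list with 11 of 34 higher and 2 lower (the same adjusted over the list alone; adjusted p = 0.017, but adjusted p = 0.248 with an estimated correlation and 0.0557 without shNT replicate 3). Of 29 fatty acid oxidation genes 11 fell and 1 rose (11 and 3 adjusted over the list alone; adjusted p = 0.00425, but adjusted p = 0.0533 with an estimated correlation), with Acaa2 at 2.10-fold, Cpt1a at 1.70-fold and Acadm at 1.59-fold lower. Of 29 sterol and fatty acid synthesis genes 20 fell and none rose (21 adjusted over the list alone; adjusted p = 1.68e-11, but adjusted p = 0.0533 with an estimated correlation), with Insig1 at 2.07-fold, Hmgcs1 at 1.99-fold and Stard4 at 1.76-fold lower. Of 31 mitophagy and autophagy genes 14 fell and 4 rose (the same adjusted over the list alone; adjusted p = 0.00943, but adjusted p = 0.248 with an estimated correlation). Bnip3l fell 1.73-fold, Sqstm1 1.42-fold and Map1lc3b 1.37-fold. Mfn2, the outer membrane fusion GTPase, fell 1.82-fold in a mitochondrial dynamics list that was not called (7 higher, 6 lower of 35).

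Of 44 cell cycle genes 14 rose and 1 fell in shOpa1 (the same adjusted over the list alone; adjusted p = 0.00527, but adjusted p = 0.535 with an estimated correlation), with the helicase subunits Mcm5 and Mcm2 at 1.59-fold and 1.49-fold. Among fibroblast genes 12 of 30 fell and 6 rose (the same adjusted over the list alone; adjusted p = 0.031, but adjusted p = 0.405 with an estimated correlation). Mfap4 fell 2.26-fold and Vim (vimentin) 1.55-fold. Of 14 epicardial markers 8 fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.00425, but adjusted p = 0.18 with an estimated correlation), Lrrn4 by 1.84-fold. The collagen list was not called (14 higher, 15 lower of 43; adjusted p = 0.622), with Lox 1.89-fold lower and Thbs1 (thrombospondin 1) 1.48-fold higher. Hephl1, a copper ferroxidase, rose 15.5-fold, Tnfsf18, a cytokine of the tumour necrosis factor family, 5.67-fold, the guidance factor Sema3a 4.27-fold and Ptx3, a soluble pattern recognition protein, 4.21-fold. Of 26 myofibroblast genes 14 fell and 5 rose (14 and 6 adjusted over the list alone; adjusted p = 0.0467, but adjusted p = 0.423 with an estimated correlation), a call that ended without shNT replicate 3 (0.08), shOpa1 replicate 1 (0.0694) or shOpa1 replicate 3 (0.0538). Macrophage and leukocyte markers had a median 1.61-fold higher and were not called (1 of 21 higher, none adjusted over the list alone; adjusted p = 0.0539, and 0.903 with an estimated correlation). They passed with DESeq2 size factors (0.0483), with the 2 groups alone (0.00498) and without shNT replicate 1 (0.00583) or shOpa1 replicate 2 (7.4e-04). None of the list calls in this comparison held with an estimated correlation.

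The double knockdown was set against the same shNT libraries as the single knockdowns, so its folds and theirs share the noise of those libraries, and their likeness was not tested. Xirp2 rose 14.1-fold, Hephl1 7.00-fold and Sema3a 4.51-fold. Hcn4 fell 3.55-fold, Myh8 (a developmental myosin heavy chain) 3.54-fold, Cpxm1 3.00-fold and Nppa 2.84-fold. Of 14162 genes 1581 were higher and 1689 lower, 149 and 118 of them by more than 2-fold, and the groups did not overlap for 3145. Sterol and fatty acid synthesis was the one list whose call held with an estimated correlation (23 of 29 lower, none higher, 25 adjusted over the list alone; adjusted p = 1.6e-18, and 0.0399 with an estimated correlation), with Elovl6 at 2.86-fold, Scd2 at 2.04-fold, Insig1 at 2.03-fold and Hmgcs1 at 1.86-fold lower. Of 42 integrated stress genes 24 rose and 3 fell (27 and 4 adjusted over the list alone; adjusted p = 1.26e-07, but adjusted p = 0.153 with an estimated correlation), among them Slc7a1 (1.45-fold), Slc7a5 (1.32-fold) and Aars (1.31-fold). Of 44 cell cycle genes 12 rose (14 adjusted over the list alone; adjusted p = 6.18e-05, but adjusted p = 0.258 with an estimated correlation), with Cdt1 at 1.64-fold and Mcm5 at 1.59-fold. The chaperone Hspd1 rose 1.61-fold, while the autophagy genes Bnip3l and Map1lc3b fell 1.55-fold and 1.34-fold in a list with 14 of 31 lower and 1 higher (14 and 2 adjusted over the list alone; adjusted p = 0.00171, but adjusted p = 0.192 with an estimated correlation).

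The sarcomere list was not called in the double knockdown against shNT (11 higher and 9 lower of 35, 12 and 9 adjusted over the list alone; median 1.10-fold; adjusted p = 0.563). Flnc (filamin C) was 1.34-fold higher, Tnnt2 1.29-fold lower and Myl4 1.31-fold lower. Of the calcium list 10 of 29 fell and 3 rose (11 and 3 adjusted over the list alone; adjusted p = 0.0181, but adjusted p = 0.236 with an estimated correlation), Gja1 by 1.81-fold and Slc8a1 by 1.37-fold. Fibroblast genes (14 of 30 lower, 3 higher, the same adjusted over the list alone; adjusted p = 9.57e-06, but adjusted p = 0.153 with an estimated correlation) included Mfap4 at 2.14-fold and Tcf21 at 1.61-fold lower. Matrix genes (22 of 43 lower, 7 higher, 23 and 8 adjusted over the list alone; adjusted p = 0.00109, but adjusted p = 0.481 with an estimated correlation) included Lox at 1.96-fold and Sparc at 1.40-fold lower. Epicardial markers (8 of 14 lower, none higher, 9 adjusted over the list alone; adjusted p = 8.11e-04, but adjusted p = 0.153 with an estimated correlation) included Lrrn4 at 1.94-fold lower. Macrophage and leukocyte markers moved with this group. Their median was 2.80-fold higher, 2 of 21 passed singly and none did so adjusted over the list alone (adjusted p = 1.67e-07, but adjusted p = 0.379 with an estimated correlation). The 2 were the complement gene C1qa (3.08-fold, adjusted p = 0.02) and the chemokine receptor Cx3cr1 (4.15-fold, adjusted p = 0.0334). With the replicate number as a block both missed the threshold (adjusted p = 0.0521 and 0.0752). C1qa also did without double knockdown replicates 1 and 3 and without each shNT library, and Cx3cr1 without each of the 6 libraries, at adjusted p from 0.0503 to 0.112.

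Also called in the double knockdown against shNT, but not with an estimated correlation, were other cardiomyocyte genes (8 of 20 lower, 1 higher; adjusted p = 0.0253, and 0.328 with an estimated correlation), myofibroblast genes (10 of 26 lower, 5 higher; 0.0205 and 0.258), mitochondrial biogenesis genes (9 of 34 higher, 2 lower; 0.00729 and 0.192) and interferon genes (3 of 44 higher, none lower; 3.06e-04 and 0.69). The first of these calls ended without double knockdown replicate 1 (adjusted p = 0.0878). The 18 lists not called had adjusted p from 0.0766 to 0.991.

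**Figure D3:**
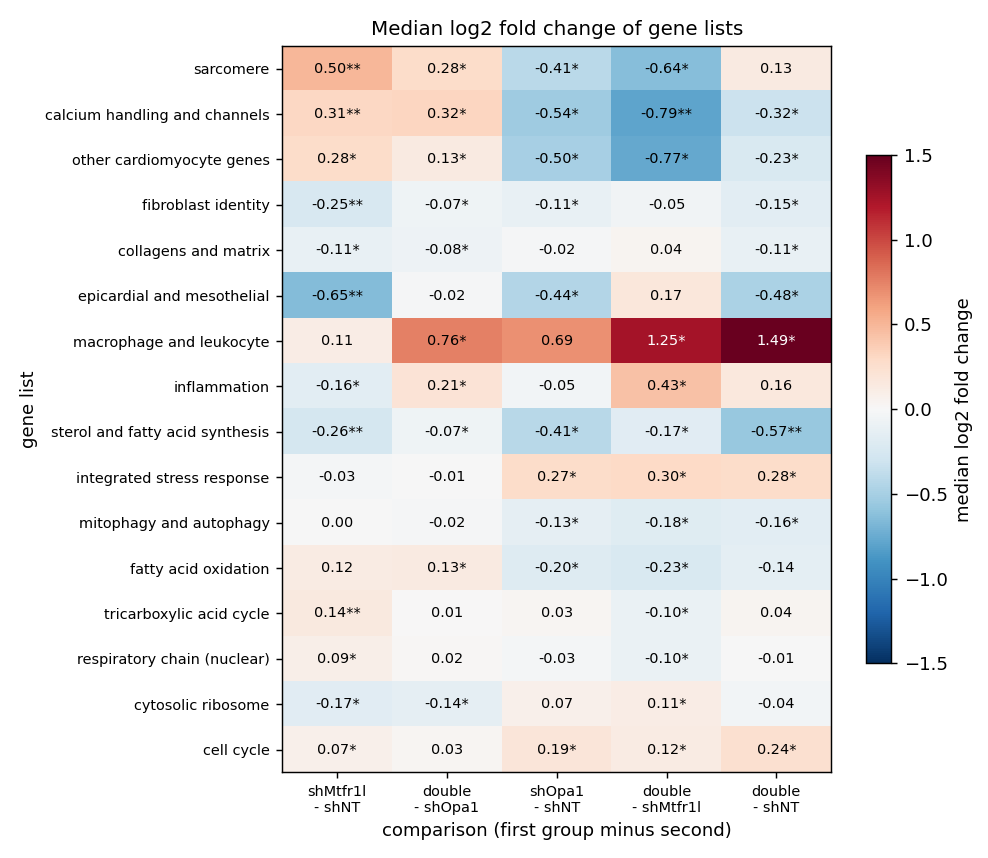
Median log2 fold change of 16 gene lists in the 5 comparisons between groups, from blue (lower in the first group named) to red (higher). A single star marks an adjusted camera p under 0.05 with the preset correlation and 2 stars one that is also under 0.05 with an estimated correlation, as for the sarcomere list in shMtfr1l against shNT (0.50).

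Knockdown of Opa1 on top of Mtfr1l knockdown was compared with Mtfr1l knockdown alone, to ask what loss of Opa1 does in those cells. Mtfr1l was itself 1.66-fold higher in the double knockdown than in shMtfr1l (adjusted p = 5.27e-06, edgeR quasi-likelihood test). A partial return of Mtfr1l therefore cannot be told apart from loss of Opa1 in this comparison. Of 29 calcium and channel genes 18 fell and 1 rose (the same adjusted over the list alone; adjusted p = 9.97e-12, and 0.0133 with an estimated correlation), with Hrc, a calcium-binding protein of the sarcoplasmic reticulum, at 5.07-fold, Sln at 2.95-fold, Gja1 at 2.62-fold and Kcnj5 at 1.93-fold lower. Of 35 sarcomere genes 25 fell and 2 rose (26 and 2 adjusted over the list alone; adjusted p = 4.22e-14, but adjusted p = 0.0656 with an estimated correlation), with Ldb3 at 1.69-fold, Tnnt2 at 1.59-fold and Myl4 at 1.47-fold lower and Xirp2 at 7.46-fold higher. Among other cardiomyocyte genes 11 of 20 fell and 1 rose (the same adjusted over the list alone; adjusted p = 1.76e-06, but adjusted p = 0.0656 with an estimated correlation), including Mb (2.47-fold) and Eno3 (2.04-fold). Of 19 cardiac transcription factors 7 fell and none rose (9 adjusted over the list alone; adjusted p = 0.00666, but adjusted p = 0.321 with an estimated correlation), among them the methyltransferase Smyd1 (3.42-fold). The 7 include the 3 vector factors Mef2c (1.15-fold, adjusted p = 0.0207), Gata4 (1.14-fold, adjusted p = 0.00851) and Tbx5 (1.15-fold, adjusted p = 0.0109). A lower vector level as a cause of the cardiac falls was not tested in this comparison and stays open. Rbm24 fell 3.92-fold and Txlnb 3.74-fold. Ppargc1a, a coactivator of mitochondrial biogenesis, fell 4.55-fold and Ppp1r3a, a glycogen-targeting phosphatase subunit, 5.18-fold. In all, 1377 of 14162 genes were higher and 1664 lower (166 and 142 by more than 2-fold), and the groups did not overlap for 2936. With the mean of the leukocyte markers as a covariate 1679 genes passed, and without replicate 1 of every group 1964 did. That mean itself differed between the groups (log2 CPM 4.30 to 4.64 in the double knockdown, 1.89 to 4.14 in shMtfr1l). The covariate can thus take away part of the group difference, and the drop does not count calls due to leukocytes.

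Of 29 fatty acid oxidation genes 12 fell and none rose in the same comparison (the same adjusted over the list alone; adjusted p = 0.00125, but adjusted p = 0.0586 with an estimated correlation), with Acaa2 at 1.76-fold and Cpt1a at 1.39-fold lower. Mfn2 was 1.68-fold lower. Of the sterol list 11 of 29 fell (12 adjusted over the list alone; adjusted p = 2.97e-06, but adjusted p = 0.151 with an estimated correlation), Hmgcs1 by 1.57-fold. Of 42 integrated stress genes 27 rose and 3 fell (28 and 3 adjusted over the list alone; adjusted p = 2.05e-10, but adjusted p = 0.0656 with an estimated correlation), such as the serine enzyme Shmt2 (1.49-fold) and Slc7a5 (1.40-fold). Of 33 inflammation genes 11 rose and 1 fell (the same adjusted over the list alone; adjusted p = 4.44e-04, but adjusted p = 0.151 with an estimated correlation), with C3 at 2.48-fold and the macrophage growth factor Csf1 at 1.68-fold, and the leukocyte markers moved with them (median 2.37-fold higher; 1 of 21 higher; adjusted p = 3.33e-09, but adjusted p = 0.349 with an estimated correlation). Hephl1 rose from 0.18 ± 0.11 to 7.23 ± 0.85 CPM, where a floor of 3 counts lies at 0.152 to 0.175 CPM in the shMtfr1l libraries, so that the fitted 37.7-fold has an imprecise base (3 counts can be as few as 2 fragments). Tlr5, the flagellin receptor, rose 6.02-fold, Ptx3 4.93-fold, Mfap5 2.81-fold and Col3a1 1.68-fold. Also called, but not with an estimated correlation, were mitophagy and autophagy genes (11 of 31 lower, 2 higher; adjusted p = 0.002, and 0.151 with an estimated correlation), the respiratory chain (12 of 77 lower, 1 higher; 0.0121 and 0.545), the tricarboxylic acid cycle (6 of 26 lower, 1 higher; 0.0419 and 0.17), the cell cycle (9 of 44 higher, none lower; 0.0261 and 0.545), antioxidant genes (9 of 30 higher, 2 lower; 0.031 and 0.195), interferon genes (1 of 44 higher, 1 lower; 0.0346 and 0.729) and cytosolic ribosomal protein genes (6 of 76 higher, none lower; 0.0275 and 0.616). All of these calls but that of mitophagy ended without at least 1 single library (adjusted p from 0.0505 to 0.571). The 15 lists not called had adjusted p from 0.0566 to 0.962.

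Mtfr1l knockdown in cells that also had Opa1 knockdown was compared with Opa1 knockdown alone. Opa1 was itself 2.04-fold higher in the double knockdown than in shOpa1 (adjusted p = 0.00745, edgeR quasi-likelihood test). A partial return of Opa1 therefore cannot be told apart from loss of Mtfr1l in this comparison. Some cardiac genes rose, and no cardiac list kept its call with an estimated correlation. Myh7 rose 3.93-fold, Myh6 2.85-fold (30.4 ± 5.72 to 86.8 ± 15.8 CPM; adjusted p = 8.22e-04), Rbm24 2.70-fold and Actc1, cardiac alpha actin, 2.12-fold. Of 35 sarcomere genes 14 rose and none fell (17 and 1 adjusted over the list alone; median 1.21-fold; adjusted p = 3.29e-12, but adjusted p = 0.112 with an estimated correlation), with Myom2 at 1.38-fold and Myl4 at 1.29-fold. Of the calcium list 6 of 29 rose and none fell (7 adjusted over the list alone; adjusted p = 2.95e-06, but adjusted p = 0.112 with an estimated correlation), with Sln at 2.20-fold, Gja1 at 1.58-fold and Kcnj5 at 1.29-fold. Of 20 other cardiomyocyte genes 4 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.0329, but adjusted p = 0.41 with an estimated correlation), and of 19 cardiac transcription factors 1 rose and none fell (adjusted p = 0.333). Of 29 fatty acid oxidation genes 6 rose and none fell (6 and 1 adjusted over the list alone; adjusted p = 0.00557, but adjusted p = 0.112 with an estimated correlation), among them Acaa2 (1.54-fold) and the lipid droplet protein Plin2 (1.499-fold). Mfn2 rose 1.34-fold and the interferon-inducible Ifi27l2a 2.67-fold. Of 43 matrix genes 14 fell and 3 rose (16 and 6 adjusted over the list alone; adjusted p = 4.91e-05, but adjusted p = 0.468 with an estimated correlation), such as tenascin C, Tnc (1.32-fold) and Col3a1 (1.28-fold). Ctgf, a transforming growth factor beta target, fell 1.31-fold, Sfrp2 2.65-fold, the Notch family ligand Dlk1 2.29-fold, Hephl1 2.21-fold and the monoamine oxidase gene Maob 1.80-fold. Of 76 cytosolic ribosomal protein genes 7 fell and none rose (8 adjusted over the list alone; adjusted p = 1.93e-08, but adjusted p = 0.41 with an estimated correlation). The leukocyte markers had a median 1.69-fold higher, with none of 21 passing singly (adjusted p = 1.79e-06, but adjusted p = 0.481 with an estimated correlation). Also called, but not with an estimated correlation, were fibroblast genes (6 of 30 lower, 1 higher; adjusted p = 0.0329, and 0.41 with an estimated correlation), Notch, Wnt and BMP targets (4 of 29 lower, 1 higher; 0.0111 and 0.164), sterol synthesis (2 of 29 lower, none higher; 0.0389 and 0.533) and, upward with no gene passing singly, the interferon (2.45e-05 and 0.698), unfolded protein response (0.00278 and 0.164) and inflammation lists (0.0288 and 0.41). These calls, save that of the unfolded protein response, and the call of the other cardiomyocyte genes ended without at least 1 single library (adjusted p from 0.0611 to 0.596).

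In that comparison 327 of 14162 genes were higher and 348 lower, 34 and 10 of them by more than 2-fold, and the groups did not overlap for 667 of the 675. The count was 416 without shOpa1 replicate 2, and 449, 409 and 423 without double knockdown replicates 1, 2 and 3. It was 370 and 199 without replicates 1 and 2 of every group, where Hephl1 (adjusted p = 0.0527 without 1), Dlk1 (0.0605 without 2) and Myh6 (0.0939 without 2) no longer passed.

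The 2 single effects of Mtfr1l knockdown, without and with Opa1 knockdown, share no library. The effect with Opa1 knockdown also holds the difference in Opa1 between the double knockdown and shOpa1. Of the 788 genes higher in shMtfr1l than in shNT, 101 were also called higher in the double knockdown than in shOpa1 (18.2 would overlap by chance for independent lists), 10 were called lower, and 62.7% had the same sign. Of the 735 lower genes 159 were also called lower (18.1 by chance), 7 were called higher and 78.2% had the same sign, against 56.1% over all tested genes. For the 2 effects of Opa1 knockdown, 835 of 2025 higher genes and 1160 of 2139 lower genes were called the same way (196.9 and 251.3 by chance), with 88.9% and 91.9% of the same sign against 72.1% over all tested genes. The Opa1 effect with Mtfr1l knockdown also holds the difference in Mtfr1l between the double knockdown and shMtfr1l.

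Whether the 2 knockdowns add up on the log scale was tested as an interaction, the effect of Mtfr1l knockdown with Opa1 knockdown minus that without. It passed for 504 genes, 222 above 0 and 282 below. Epicardial markers gave the one list whose interaction held with an estimated correlation (median log2 interaction 0.72; 3 of 14 passed, all above 0, 9 adjusted over the list alone; adjusted p = 1.37e-07, and 0.048 with an estimated correlation). Lrrn4 had an interaction of 0.82 ± 0.13 (SE; adjusted p = 8.76e-05), with 90.0, 48.6, 48.8 and 46.4 CPM in shNT, shMtfr1l, shOpa1 and the double knockdown. For Vcam1 it was 0.76 ± 0.079 (adjusted p = 5.77e-08) and for Lox 0.69 ± 0.059 (adjusted p = 7.7e-10). Sarcomere genes had a median of -0.33 (9 of 35 below 0, none above; 17 and 2 adjusted over the list alone; adjusted p = 2.91e-07, but adjusted p = 0.193 with an estimated correlation), with Csrp3 at -0.82 ± 0.15 (adjusted p = 6.8e-04). Collagen and matrix genes had a median of -0.0033, a mean of 0.085 and an upward test direction (11 above and 3 below 0 of 43; adjusted p = 0.136). The interaction of Mtfr1l itself was 0.78 ± 0.15 (adjusted p = 0.00146, and 0.108 without replicate 2 of every group). Without replicate 1 or 2 of every group 222 (131 above 0 and 91 below) and 161 genes (79 and 82) passed, so the balance of signs is not stable. Myh6, Myh7, Myh8 and Actc1 have close paralogs and ribosomal protein genes have many pseudogenes, and reads that map to several places were not counted, so the levels of these genes are uncertain.

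**Figure D4:**
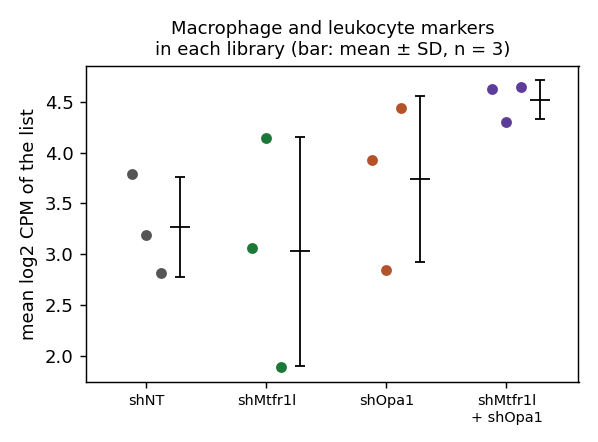
Mean log2 CPM of the 21 tested macrophage and leukocyte markers in each library, with 1 point per library and a bar for the mean ± SD of each group (n = 3). The double knockdown libraries lie between 4.30 and 4.64, above the 3.79 of the highest shNT library, while the shMtfr1l libraries spread from 1.89 to 4.14 and the shOpa1 libraries from 2.84 to 4.44, so that 1 of these lies above the lowest double knockdown library.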

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

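The leukocyte covariate, the vector factor test and the regrouping within replicate numbers were chosen after the results were seen, while the test of the weaker knockdown, with its ratios of falls and rises, and the regrouping of all libraries were set down before. The results of this part stand out because the effect of Mtfr1l knockdown differed with and without Opa1 knockdown, by the test of the interaction (edgeR quasi-likelihood, adjusted p under 0.05), which passed for 504 genes. Values are log2 interactions, given for each gene named in any comparison whose interaction passed.

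Of 33 inflammation genes 6 passed (7 adjusted over the list alone) and of 14 epicardial genes 3 (9 over the list alone), all above 0. None of 21 leukocyte genes passed singly, although their list moved the same way (camera adjusted p = 2.47e-05, but 0.552 with an estimated correlation). The named ones were Saa3 at 3.81, C3 at 0.81, Vcam1 at 0.76, Relb at 0.73, Icam1 at 0.60, Bnc1 at 0.90, Lrrn4 at 0.82 and Msln at 0.72. Of fibroblast and matrix genes, Lox lay at 0.69, Timp1 at 0.69, Fmod at 0.68, Cthrc1 at 0.61, Lum at 0.55, Mfap4 at 0.49, Tcf21 at 0.43, Fbln2 at 0.38, Col3a1 at 0.31 and Sparc at 0.18, while the collagen and matrix list as a whole was not called (11 above and 3 below 0 of 43, 12 and 11 adjusted over the list alone; median -0.0033, adjusted p = 0.136) and the fibroblast list had 8 above and 1 below 0 of 30. Chl1 (1.44), Cpxm1 (0.75), Hsd17b7 (0.70), Insig1 (0.46), Sqle (0.40), Hmgcs1 (0.34), Ndrg1 (0.92), Ddit4 (0.69), Plin2 (0.34), Ifi27l2a (1.20), Pvalb (1.27) and Mtfr1l itself (0.78) were also above 0. The named cardiac genes that passed lay below 0, with Mb at -1.22, Xirp2 at -1.11, Synpo2l at -0.97, Trdn at -0.84, Csrp3 at -0.82, Sln at -0.61, Myom1 at -0.59, Atp2a2 at -0.41, Ankrd1 at -0.39, Myom2 at -0.34 and Flnc at -0.26. Galnt16 (-1.504), Frem2 (-1.13), Pdk2 (-0.69), Lpl (-0.48), Hspd1 (-0.41), Hk2 (-0.36), Idh2 (-0.34), Ctgf (-0.33) and Slc7a1 (-0.28) were below 0 as well. Of these 50 genes 18 no longer passed when 1 library was left out (adjusted p up to 0.186), 30 when 1 replicate number was left out of every group (up to 0.512), 8 with the replicate number as a block and 7 with the leukocyte covariate. Those that passed in every alternative were Saa3, Vcam1, Icam1, Lrrn4, Lox, Timp1, Fmod, Cthrc1, Mfap4, Fbln2, Col3a1, Ndrg1, Synpo2l, Csrp3, Myom1, Ankrd1, Galnt16, Lpl and Ctgf. Genes were also named from comparisons that share libraries with the interaction, which favours signs against those effects. Among genes called in shMtfr1l against shNT, 219 of 222 called interactions went against the rises and 157 of 159 against the falls. Named genes whose interaction did not pass are not listed.

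Lists called with camera's preset correlation had median interactions of -0.33 (sarcomere), -0.13 (calcium and channels), -0.078 (respiratory chain), -0.093 (tricarboxylic acid cycle), 0.18 (fibroblast), 0.53 (leukocyte), 0.72 (epicardial), 0.52 (inflammation) and 0.23 (sterol synthesis). With an estimated correlation the epicardial call held at adjusted p = 0.048, and the others lay between 0.0966 and 0.586. The respiratory chain call also ended without shNT replicate 2 (adjusted p = 0.0994) or 3 (0.218), shMtfr1l replicate 2 (0.0685) or 3 (0.0888) and double knockdown replicate 3 (0.125).

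The smaller effect of Mtfr1l knockdown beside Opa1 knockdown could come from the weaker Mtfr1l knockdown in the double knockdown, where the log2 reduction was 0.637 of that without Opa1 knockdown (0.580 to 0.684 over left-out libraries). For the 200 largest falls of the first set the median effect went from -0.47 to 0.15, a ratio of -0.321 (-0.370 to -0.209), or from -0.44 to 0.012 with the leukocyte covariate. An effect at or beyond 0 on the other side in either set was the bound written before. The falls met it without the covariate over all left-out libraries (0.098 to 0.173). With the covariate the range was -0.041 to 0.042, so the bound was not met over all of them. The falls were picked from a pair whose leukocyte list was itself lower (median log2 difference -0.75, percentile 0). Leukocyte content can therefore move these genes, and the test cannot decide against weaker knockdown. For the 200 largest rises the effect went from 0.42 to 0.36, a ratio of 0.873 (0.694 to 1.03) that lay above the one of the knockdown and reached 1, so a smaller effect on them was not shown. Weaker knockdown stays open, in part or as the whole cause. A lower level of the vector factors also stays open, as 0 of Mef2c, Gata4 and Tbx5 had a called interaction while all 3 lay below 0. Weaker Opa1 knockdown in the double knockdown, where Opa1 was 2.04-fold higher than in shOpa1, was not tested and stays open too. Among genes called in shOpa1 against shNT, 215 of 222 called interactions went against the rises and 171 of 180 against the falls. That comparison shares libraries with the interaction, which favours such signs, so these counts cannot decide. The biological reading, that loss of Opa1 limits what loss of Mtfr1l does, was not tested apart from these explanations.

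In 100 groupings of the 12 libraries into 4 groups of 3, the real one included, 2 gave as many interactions as the real 504, the other 772. That other grouping put at least 5 of 6 libraries of 1 knockdown on one side, and among 83 groupings with at most 4 there the highest count was 23. When libraries were exchanged within replicate numbers alone, 4 of 60 groupings gave as many, with up to 1640, so chance is not excluded there, and among 50 with at most 4 on one side the highest was 232. Regroupings put libraries of different knockdowns into 1 group, so the effects of the knockdowns widen the spread within groups. Low counts there do not measure how many calls chance gives.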

How the results depend on the processing

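The leukocyte covariate and the removal of each replicate number from every group were added after the data were seen. Counts of called genes are given in the order shMtfr1l against shNT, shOpa1 against shNT, double knockdown against shNT, against shMtfr1l and against shOpa1, and interaction, where the reported counts are 1523, 4164, 3270, 3041, 675 and 504. They were 1494, 4144, 3261, 3034, 674 and 480 with DESeq2 size factors, 1643, 4302, 3411, 3237, 880 and 668 without a filter, and 1617, 4190, 3408, 3180, 788 and 622 with the DESeq2 Wald test. Fits of the 2 groups alone gave 1396, 4053, 3642, 3160 and 748, and the first-set pair added gave 1420. With the replicate number as a block they were 1387, 4003, 3071, 2846, 576 and 411, and among the named genes the block ended the calls of C1qa (adjusted p = 0.0521), Cx3cr1 (0.0752), Gata4 (0.0777) and 8 of 50 interactions (0.0559 to 0.0774), and of no list. With the leukocyte covariate they were 1617, 4152, 2210, 1679, 584 and 437. All double knockdown libraries lay above every shNT library in that covariate, so it can also take away part of that group's effect.

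With libraries left out, singly or as 1 replicate number of every group, the counts ran from 790 to 1289, 3020 to 3754, 2185 to 2914, 1964 to 2876, 199 to 589 and 161 to 539. Fewer libraries were fitted there, and the cause was not tested further. For shMtfr1l against shNT 790 and 878 passed without replicates 1 and 2 of every group, and for the double knockdown against shMtfr1l 1964 without replicate 1. Against shOpa1, 416 passed without shOpa1 replicate 2, 449, 409 and 423 without double knockdown replicates 1, 2 and 3, and 370 and 199 without replicates 1 and 2 of every group, where the interaction had 222 and 161.

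Some list medians turned against the reported sign or test, and the cause was not tested. With libraries left out, the leukocyte list in shMtfr1l against shNT ran from -0.74 to 0.56, and it was 0.50 with an upward test without shMtfr1l replicate 3 (adjusted p = 0.0254). The interferon list ran from -0.031 (without shMtfr1l replicate 3) to 0.33 in that comparison, from -0.025 to 0.61 in the double knockdown against shOpa1 and from -0.44 to 0.60 in the interaction, and the cytosolic ribosome list from -0.081 to 0.16 in the interaction, each lowest without replicate 1 of every group where not named otherwise. The share of called genes with the same sign in the first-set pair was 84.46% at an adjusted p of 0.01 against 82.16%. No named gene or gene of the naming rule that was called turned direction in any alternative. The names in the text were chosen with the effect of left-out libraries in view, so their stability is not that of all called genes. The 3 fits of the first set that include fibroblasts were not run, and lists were not tested with DESeq2.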

Other observations

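The tests of vector factors and of leukocyte markers and the genes of the first paragraph were chosen after the values were seen, while the test of gene length and the splits of 6 libraries were set down before. Several genes moved in opposite directions in the 2 single knockdowns, each against the same shNT libraries (edgeR quasi-likelihood). Sfrp2, the secreted Wnt modulator, stood at 7.01 ± 1.63, 2.22 ± 0.56, 25.5 ± 0.43 and 9.64 ± 1.24 CPM (SD, n = 3) in shNT, shMtfr1l, shOpa1 and the double knockdown, and rose 3.63-fold in shOpa1 (adjusted p = 2.35e-10). Hephl1 stood at 1.03, 0.18, 16.005 and 7.23 CPM in that order and fell in shMtfr1l (adjusted p = 1.67e-04) to near the floor of 3 counts (0.152 to 0.175 CPM there). The pattern recognition gene Ptx3 fell 1.87-fold in shMtfr1l (adjusted p = 9.54e-07, but 0.0594 with the first-set pair added) and rose in shOpa1 (15.96, 8.53, 67.3 and 42.0 CPM). Mfap5 rose 2.03-fold in shOpa1 (adjusted p = 1.68e-08), Jag1 1.61-fold (adjusted p = 8.68e-09), C3 1.41-fold (adjusted p = 0.00274) and Col3a1 1.36-fold (adjusted p = 5.6e-13), and all of these fell in shMtfr1l. In a principal component analysis of the 12 libraries, component 1 (29.07% of variance) put all shNT and shMtfr1l libraries below 0 and all libraries with Opa1 knockdown above 0.

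Higher sarcomere genes after Mtfr1l knockdown were weighed against gene length and vector dose. The median of the sarcomere list (log2 0.50) lay at percentile 100 of 10000 random lists matched on exon length, whose highest median was 0.275, which argues against length. The vector factors were higher for 3 of 3 (Mef2c 276 to 325, Gata4 481 to 538 and Tbx5 322 to 370 CPM), with calls that each ended without some single libraries, so a higher vector level stays open. In the double knockdown against shOpa1, where 14 of 35 sarcomere genes also rose (list adjusted p = 3.29e-12, but 0.112 with an estimated correlation), none of the 3 was called (1.05-fold to 1.06-fold by value). Opa1 was 2.04-fold higher there as well, so that rise cannot be put down to loss of Mtfr1l alone. The biological reading, that loss of Mtfr1l favours the cardiac programme, was not tested apart from these.

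Higher leukocyte markers in the double knockdown could come from more leukocytes in those libraries. Within groups the markers' deviations had a median pairwise correlation across libraries of 0.897, where the highest of 200 random lists gave 0.12. All 16 of 16 markers with a mean of at least 10 CPM over the 12 libraries were higher by value in the double knockdown than in shNT, such as Csf1r (28.2 to 92.1 CPM, adjusted p = 0.0559) and Lyz2 (227 to 372 CPM, adjusted p = 0.305), and none of the markers is in another list. That mean includes the double knockdown, so markers high there, such as Ptprc (7.94 CPM in shNT and 26.8 in the double knockdown), pass the cut more easily. The cut thus favours 16 of 16. Of the scarcer markers, S100a8 (1.07 to 0.0536 CPM, adjusted p = 0.0885) and Cd74 (1.43 to 0.858 CPM, adjusted p = 0.788) were lower by value. The values of the other markers are what more leukocytes would give, and no sorting of the cells is named. Whether a knockdown drew or spared such cells was not tested.

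In the 10 splits of each 6 libraries into 3 and 3, the real one gave the most called genes each time (1 of 10, too few for a share under 0.05). The highest other split had 0 genes against 1523, 4164, 3270 and 3041, and 1 against 675 for the double knockdown against shOpa1. The other splits mix libraries of both groups, so the knockdown itself widens the spread within each side. Their low counts do not measure how many calls chance gives.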
